A study of Bacillus subtilis with 9 samples.

How the data were processed

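RNA of Bacillus subtilis BSB1, a tryptophan-prototrophic derivative of the laboratory strain 168, was measured on 2-colour Agilent arrays in 9 chemostat cultures. Per the labels, all cultures were limited by glucose (1 g/l) and grew at 0.1 per h in a minimal medium. The 3 groups were a reference with no added salt, 1.2 M NaCl (70.13 g/l), and 1.2 M NaCl with 1 mM glycine betaine (117.15 mg/l), called here reference, NaCl and NaCl_GB. Each group held 3 arrays from 3 biological replicates. The labels place the RNA of each sample in the Cy5 channel and a common pool, made up in equal parts from the 9 cultures, in the Cy3 channel of every array, with no swap of the dyes.

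The gene table deposited by the authors holds, for each of 4105 annotated genes and each array, a ratio of sample to pool on a linear scale. Per the file header, these ratios are error-weighted averages of the probe ratios of a gene in the SubtiList annotation, made in Rosetta Resolver 7.2.1 without pooling arrays. The submitters' processing notes name Agilent Feature Extraction 10.5 for the scanner data. A normalization between arrays is not stated. The median ratios were 0.882, 0.937 and 0.903 in reference replicates 1, 2 and 3, 1.06, 1.06 and 1.05 in NaCl, and 0.982, 0.988 and 0.980 in NaCl_GB. The second table deposited by the authors holds values on a log10 scale for 41882 probes that carry no gene names, so it gave no value per gene. Its base was read from the values: the SD of the log10 gene ratios lay between 0.230 and 0.386 across arrays, and that of the probe values between 0.225 and 0.339. The centring of the probe values is not stated; their medians were 0 in the 3 reference arrays, 0.0342, 0.0402 and 0.0203 in NaCl, and 0.0081, 0.0117 and 0 in NaCl_GB. Their direction, sample over pool, is taken from the design and is not stated for that table. Of the 4105 genes, 4037 locus tags matched the reference gene table of assembly ASM904v1, and 1027 current symbols differ from the deposited ones. The deposited symbol is used here, with the current symbol added where it helps. The build behind the deposited files is not named, so no coordinates are given.

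The ratios were converted to log2. Since every ratio shares the pool, a difference between groups of log2 ratios is taken as a log2 fold change between cultures. A ratio holds no level of signal, so no filter on low values was possible, and the number of arrays, 3 per group, limits the precision. One model with 3 group means was fitted to all 9 arrays in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation, 2-sided tests and Benjamini-Hochberg adjustment over 4105 genes. A gene was called at an adjusted p under 0.05, separately in NaCl against reference, NaCl_GB against reference and NaCl_GB against NaCl. A moderated F test compared the 3 groups at once. Errors beside log2 changes are standard errors of this model, and errors beside ratios are SDs over 3 arrays.

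A total of 43 gene lists (pathways, regulons, prophage and stress genes) were tested with camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 43 lists. Camera compares a list with all other genes. Beside each called list stands its adjusted p with an estimated correlation. Member counts are adjusted over all genes, and where they differ the count adjusted over the list alone is added. Genes named in the text follow a rule: per comparison, the 10 largest rises and 10 largest falls among called genes whose 3 arrays of one group all lay above the 3 of the other; 14 genes of osmoprotection in every comparison; and up to 4 called members of each list with the largest changes, or the largest member where none was called. Exceptions are said to have been chosen after their values were seen. The groups, tests, gene lists, the rule for named genes and all alternative settings not marked otherwise were chosen before the data were examined.

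Alternatives covered the scaling of the arrays (median centring, quantile normalization), a pseudocount, the variance model, array weights, the arrays in the fit, a replicate block, a 2-fold minimum, an ordinary linear model, the list test, and leaving out each array in turn. Weights per group, the counts of called probes and a replicate block in the reference and NaCl_GB arrays alone were added after seeing the data. The block followed a check of the values: after removal of the group means, 4 of 9 pairs of arrays with the same number correlated above 0.1, and all 3 pairs of reference and NaCl_GB were among them (0.337, 0.403 and 0.191). Reference and NaCl_GB pairs with different numbers lay between -0.364 and 0.172, and 7 of 9 arrays correlated best with their own number. Other pairs went against this: different-number pairs of reference and NaCl reached 0.337, and their same-number pairs lay at -0.304, -0.345 and -0.0014. The labels state no shared batch or day for a number, so the check does not show that the numbers pair cultures. The analysis was tested on simulated data with the measured spread of each group, with 100 genes changed by 0.5 and 100 by 1 on the log2 scale among 4105. In the NaCl against reference step, 50% and 73% of these were called with the right sign, and 78 of 3852 unchanged genes were called. With weights per group the values were 30%, 58% and 26 unchanged genes, and with equal spread in all groups they were 36%, 69% and 5. With the measured spread, with or without these weights, false calls thus made up more of all calls than the adjusted p threshold allows. With equal spread they did not. The share of false calls among the genes called in the measured data was not estimated. Overlaps between comparisons that share 3 arrays were set beside 100 simulated data sets with no effect. Figures were drawn with matplotlib 3.10.9.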

Results

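Transcript ratios of 4105 genes were measured in 9 glucose-limited chemostat cultures of B. subtilis. There were 3 without added salt (reference), 3 with 1.2 M NaCl, and 3 with 1.2 M NaCl and 1 mM glycine betaine (NaCl_GB), a compatible solute that the cells can take up. All cultures were set to the same growth rate. The arrays report ratios to a common pool and no counts, and 3 arrays per group limit the precision. Replicates lay closest in NaCl, with a median SD per gene of 0.0638 on the log2 scale and Pearson r across genes of 0.989 to 0.993. They were a little farther apart in NaCl_GB (0.0949, r = 0.931 to 0.972) and farthest apart in the reference (0.253, r = 0.408 to 0.859). Between groups, r across genes ran from -0.517 to 0.156 for reference and NaCl, from -0.255 to 0.309 for reference and NaCl_GB, and from 0.507 to 0.633 for NaCl and NaCl_GB. Reference replicate 2 stood apart: its r was 0.136 to 0.156 with NaCl, where replicates 1 and 3 lay between -0.517 and -0.308. With NaCl_GB it was 0.252 to 0.309, against -0.255 to 0.031 for replicates 1 and 3. Its r was 0.408 and 0.652 with reference replicates 1 and 3, which correlated at 0.859. Genes are not independent replicates, and r is given only to describe the arrays. Of the 4105 genes, 3421 differed among the 3 groups in limma's F test.

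The first comparison, NaCl against reference, asks which genes respond to sustained high salinity when no osmoprotectant is supplied. Genes for making the compatible solute proline were higher in NaCl. The gene proH (BSU18480), a pyrroline-5-carboxylate reductase of the osmotic route, rose by 2.90 ± 0.33 on the log2 scale (7.47-fold, adjusted p = 9.9e-05). Its neighbour proJ (BSU18470), the glutamate kinase of that route, rose by 2.83 ± 0.28 (7.12-fold). All 6 measured genes of proline synthesis rose, including proA (0.62 ± 0.13), proB (0.79 ± 0.12), proI (0.79 ± 0.10) and proG (1.12 ± 0.11). The list median lay 0.78 above that of all genes (camera adjusted p = 0.0459; adjusted p = 0.81 with an estimated correlation). Without reference replicate 2 the list was not called (adjusted p = 0.065). The proline transporter gene opuE (BSU06660) rose 12.5-fold (3.64 ± 0.20). Genes of proline breakdown rose as well. The proline dehydrogenase gene ycgM (putB, BSU03200) rose 22.1-fold (4.46 ± 0.21), ycgN (putC, BSU03210) 16-fold, and the proline importer gene ycgO (putP) by 2.20 ± 0.07. These were 3 of the 4 members of the proline use list, which was not called (camera adjusted p = 0.0529). It was called after quantile normalization (0.0246), without NaCl replicate 1 (0.0433) or 2 (0.0454), with weights per group (0.0385) and by fry (3.1e-07).

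Of 13 genes for uptake of compatible solutes, 9 rose and 4 fell in NaCl. The opuA operon of a glycine betaine importer was among those that rose, with opuAA (BSU02980) up 3.73-fold, opuAB by 1.49 ± 0.10 and opuAC by 1.41 ± 0.10. So did opuBA of the choline importer OpuB (1.28 ± 0.10) and the glycine betaine transporter gene opuD (0.77 ± 0.14). The 4 that fell were the genes of OpuC, an importer with a broad range of substrates, with opuCA (BSU33830) at -1.32 ± 0.08 (adjusted p = 4.9e-06). The mean over the opuC operon was -1.24 ± 0.08 and that over the opuB operon 0.996 ± 0.101; both operon means were chosen after the values were seen. The uptake list as a whole was not called by camera (adjusted p = 0.429), but was by fry (0.000875). All 4 genes of the list of glycine betaine synthesis from choline, which holds enzyme genes and regulator genes, rose. The enzyme genes gbsA (BSU31060) and gbsB rose by 2.06 ± 0.24 and 1.85 ± 0.23, and the regulator genes yvbF (opcR) and yuaC (gbsR) by 2.18 ± 0.09 and 1.06 ± 0.14. This list missed the threshold as well (camera adjusted p = 0.0529), but was called after median centring (0.0303) or quantile normalization (0.0434), without reference replicate 3 (0.0479), with weights per group (0.0320) and by fry (1.9e-05).

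**Figure D1:**
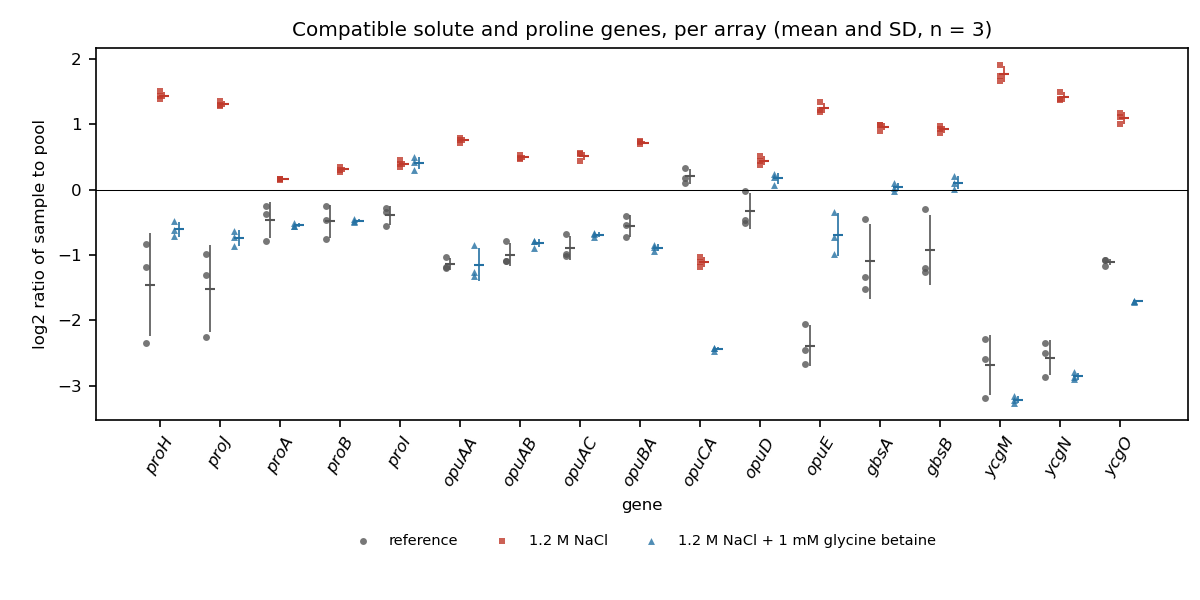
Log2 ratio of sample to pool (vertical axis) for 17 genes of proline and compatible solute metabolism (horizontal axis), with 1 symbol per array and the mean and SD of 3 arrays beside each group. In NaCl, proH, proJ, opuE and ycgM lie above the pool in all 3 arrays, while opuCA lies below the pool in NaCl and lower still in NaCl_GB.

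The largest rises in NaCl were those of yqiI (BSU24190), 125-fold at 6.97 ± 0.20, and its neighbour yqiH, 26.2-fold at 4.71 ± 0.49. Of the yit genes, yitN, yitO and yitP rose between 20.4-fold and 24.5-fold. The genes dhbB, dhbC and dhbE of bacillibactin synthesis, a siderophore, rose by 4.34 ± 0.17, 4.27 ± 0.22 and 3.79 ± 0.21. The largest falls were those of genes expressed late in sporulation. The spore coat genes cotG (BSU36070), cotV, cotX, cotW and cotY lay at -9.20 ± 1.06, -9.06 ± 0.93, -8.86 ± 0.94, -8.11 ± 0.94 and -7.97 ± 0.84. The small acid-soluble spore protein gene sspG lay at -8.48 ± 0.88, and the spore crust genes cgeA and cgeB at -8.36 ± 0.83 and -7.79 ± 0.78. Also among these falls, yjcC (spoVIF) and yurS lay at -7.79 ± 0.78 and -7.75 ± 0.70. Reference arrays spread widely for these genes, and the ratio of cotG to the pool was 35.7 in reference replicate 1. In NaCl these genes lay near the bottom of the arrays. The 9 neighbouring genes from yjbX to yjcC, which include cotV to cotY, had median log2 ratios of -7.13, -6.35 and -6.70 in NaCl. The lowest ratios of any gene on these arrays were 0.0041, 0.0088 and 0.0079. Since ratios hold no level of signal, the sizes of these falls are uncertain.

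In the fixed lists, 51 of 52 genes of flagella and chemotaxis fell in NaCl (camera adjusted p = 3.02e-26; adjusted p = 0.381 with an estimated correlation). Their median lay at -2.91 relative to all genes. The flagellin gene hag (BSU35360) fell 53.6-fold (-5.74 ± 0.21), the motor genes motA and motB lay at -4.31 ± 0.29 and -4.05 ± 0.30, and the chemoreceptor gene mcpC at -4.16 ± 0.26. Of 50 sporulation genes, 46 fell and 0 rose (7.92e-10; adjusted p = 0.82 with an estimated correlation), at a median of -3.03 relative to all genes. Of 71 genes for use of carbon sources other than glucose, 55 fell and 5 rose (56 and 5 adjusted over the list alone). Their median lay at -1.64 relative to all genes (5.86e-12; adjusted p = 0.82 with an estimated correlation), and araA, araQ, araM and araL of arabinose use lay between -4.17 ± 0.27 and -3.38 ± 0.31. Of 16 purine synthesis and salvage genes, 14 fell and 1 rose (5.54e-05; adjusted p = 0.82 with an estimated correlation). The xanthine permease gene pbuX lay at -2.65 ± 0.16, xpt at -2.25 ± 0.13, purH at -1.38 ± 0.15 and purD at -1.36 ± 0.15.

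Of 11 genes of autolysins and wall turnover, 7 fell and 3 rose in NaCl (camera adjusted p = 0.0347; adjusted p = 0.81 with an estimated correlation). The autolysin genes lytF and lytD lay at -3.66 ± 0.09 and -3.42 ± 0.10, and yoeB (iseA), which encodes an inhibitor of autolysins, at -4.69 ± 0.24. Without reference replicate 1 or 2 this list was not called (adjusted p = 0.0523 and 0.0606). In the phosphate starvation list, 10 of 19 members fell and 1 rose (camera adjusted p = 0.03; adjusted p = 0.81 with an estimated correlation). The phosphatase genes phoB and phoA lay at -2.57 ± 0.47 and -1.55 ± 0.15, and phoD rose by 1.61 ± 0.13. Only 4 members fell without NaCl replicate 1, and the list was not called without reference replicate 1 (adjusted p = 0.0631).

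Other lists rose in NaCl. Of 34 genes of the Fur regulon of iron limitation, 28 rose and 4 fell, at 0.79 relative to all genes (camera adjusted p = 0.00046; adjusted p = 0.82 with an estimated correlation). Of 25 genes for sulfate assimilation and cysteine synthesis, 18 rose and 1 fell (0.00231; adjusted p = 0.81 with an estimated correlation). The largest rises there were those of ytmI (3.53 ± 0.28), ytmK (2.43 ± 0.25) and ytmL (2.27 ± 0.17). Of 18 genes of potassium and sodium transport, 14 rose and 2 fell (0.00839; adjusted p = 0.82 with an estimated correlation). The genes mrpA (BSU31600) to mrpD of the Mrp sodium-proton antiporter rose by 2.05 ± 0.15 to 2.48 ± 0.13. Of 36 genes for surfactin, bacilysin and other antimicrobials, 25 rose and 4 fell (0.00238; adjusted p = 0.81 with an estimated correlation), with yvaX at 3.25 ± 0.19 and yvaW at 3.09 ± 0.19. Of 24 competence genes, 21 rose and 1 fell (0.0154; adjusted p = 0.82 with an estimated correlation). The gene comS, whose product stabilizes the competence regulator ComK, rose by 2.50 ± 0.12 and comC by 2.13 ± 0.24, while comER lay at -4.63 ± 0.64.

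Of 22 genes for fatty acid and membrane lipid synthesis, 15 rose and 2 fell in NaCl (camera adjusted p = 0.05; adjusted p = 0.82 with an estimated correlation). The desaturase gene des was lower (-2.61 ± 0.19) and psd, a phosphatidylserine decarboxylase gene, higher (1.47 ± 0.14). This list missed the threshold after median centring (adjusted p = 0.0639), with weights per group (adjusted p = 0.0516) and without any 1 array except NaCl replicate 1 (adjusted p = 0.0504 to 0.0609). Of 30 genes of the defective prophage PBSX, 27 rose and 1 fell (28 and 1 adjusted over the list alone), with xpf at 2.82 ± 0.57 and xkdB at 2.72 ± 0.48 (camera adjusted p = 0.0374; adjusted p = 0.895 with an estimated correlation). Only 8 rose without reference replicate 1, reference replicate 3 or NaCl replicate 2, 10 without NaCl replicate 1 and 9 without NaCl replicate 3. The prophage list was not called without reference replicate 1 (adjusted p = 0.0767) or reference replicate 3 (adjusted p = 0.0732).

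In all, 3026 of 4105 genes (73.7%) were called in NaCl against reference, 1806 higher and 1220 lower, and 1566 of them changed at least 2-fold. In data simulated with the unequal spread of the groups, false calls in this comparison exceeded the share that the adjusted p allows. Their share among the called genes here was not estimated. The 3 arrays of one group lay above the 3 of the other for 3108 genes (75.7%, against 10% by chance), 2974 of them called. They did so for every called gene named for this comparison, as the naming rule required of the largest rises and falls. The median change of all genes was 0.18 on the log2 scale. With that shift removed by centring each array, 2991 genes were called, and the share of called genes that were higher went from 59.7% to 48.2%. Of the 43 lists, 14 were called, 8 up and 6 down, each with separate array medians in the 2 groups. With an estimated correlation camera called 0 lists, and 1 had an unadjusted p under 0.05. The general stress regulon of sigma B was not called. In it, 24 of 70 genes rose and 14 fell (19 and 11 adjusted over the list alone), and its median of 0.17 changed sign when the arrays were rescaled. After median centring 16 rose and 23 fell, after quantile normalization 17 rose and 20 fell, and without any 1 array 16 to 32 rose and 8 to 17 fell.

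The second comparison, NaCl_GB against reference, differs in both salt and glycine betaine, so that the changes below belong to the 2 together. The sigma B general stress regulon was higher in NaCl_GB, where 59 of 70 members rose and 0 fell (60 and 0 adjusted over the list alone). Its median lay at 1.34 relative to all genes (camera adjusted p = 3.8e-10; adjusted p = 0.81 with an estimated correlation), and yjgB (BSU12150), yhxD and ydaD rose by 3.19 ± 0.21, 3.05 ± 0.24 and 3.04 ± 0.28. Genes of iron limitation, for bacillibactin and for flavodoxins, gave the 10 largest rises. Of bacillibactin synthesis, dhbB rose by 5.78 ± 0.17 (55-fold), dhbC by 5.68 ± 0.22, dhbE by 5.38 ± 0.21, dhbA by 5.26 ± 0.26 and dhbF by 4.77 ± 0.23. The flavodoxin genes ykuN and ykuP rose by 5.68 ± 0.10 and 5.15 ± 0.11, ykuO between them by 5.37 ± 0.10, and feuC and feuA of bacillibactin uptake by 4.76 ± 0.15 and 4.72 ± 0.19. In the Fur regulon 25 of 34 members rose and 4 fell, at 1.74 relative to all genes (2.45e-07; adjusted p = 0.81 with an estimated correlation).

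The largest fall in NaCl_GB was that of wapA (BSU39230), which encodes a wall-associated toxin of contact-dependent inhibition, at -5.05 ± 0.21 (33.1-fold lower). Its neighbours yxxG, yxiF and yxzC lay at -4.35 ± 0.34, -4.22 ± 0.23 and -4.03 ± 0.18. The wall hydrolase genes cwlC and cwlH of the sporulating mother cell lay at -4.84 ± 0.67 and -4.66 ± 0.67, sspG at -4.72 ± 0.88, yurS at -4.33 ± 0.70, yclG at -4.02 ± 0.60 and ywrK at -3.89 ± 0.65. Of 50 sporulation genes, 40 fell and 1 rose (42 and 1 adjusted over the list alone), at -1.90 relative to all genes (camera adjusted p = 1.52e-07; adjusted p = 0.81 with an estimated correlation). The number that fell was 25 without reference replicate 1, 17 without reference replicate 3 and 15 without NaCl_GB replicate 2. Of 52 genes of flagella and chemotaxis, 29 fell and 4 rose, at -0.57 relative to all genes (1.91e-05; adjusted p = 0.81 with an estimated correlation). Among them, mcpC lay at -1.28 ± 0.26, fliG at -0.90 ± 0.11 and tlpA at 1.05 ± 0.20.

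Among the osmoprotection genes, opuE (1.70 ± 0.20), gbsA (1.14 ± 0.24), gbsB (1.03 ± 0.23), proI (0.80 ± 0.10) and opuD (0.50 ± 0.14) were higher in NaCl_GB than in the reference. With a replicate block in these 2 groups alone, opuD, proJ and opuBA kept the same changes but were not called (adjusted p = 0.0822, 0.0562 and 0.104). The change of proH was 0.85 ± 0.33 with an adjusted p of 0.053, and that of proJ 0.78 ± 0.28 with an adjusted p of 0.041. The call of proJ was lost under median centring (0.66) and without any 1 array except reference replicates 1 and 2 (0.72 to 0.88). The genes opuAA, opuAB and opuAC lay at -0.01 ± 0.13, 0.17 ± 0.10 and 0.21 ± 0.10 and were not called; the latter pair was called without reference replicate 2 (0.28 and 0.31). Lower values were found for opuBA (-0.33 ± 0.10, adjusted p = 0.017), not called without NaCl_GB replicate 3 (-0.31). The mean over the opuB operon was -0.06 ± 0.10. The opuC genes fell further, opuCA to -2.65 ± 0.08 (6.26-fold lower, adjusted p = 7.7e-07), opuCB to -2.11 ± 0.08 and opuCC to -1.84 ± 0.08, with a mean of -2.04 ± 0.08 over the operon. In the proline use list, 2 of 4 genes fell, the regulator gene ycgP (putR) at -1.88 ± 0.11 and ycgO at -0.60 ± 0.07 (camera adjusted p = 0.0305; adjusted p = 0.81 with an estimated correlation). Adjusted over the list alone 3 fell. All 4 fell without reference replicate 2, and the list was not called without reference replicate 1 (adjusted p = 0.0742) or after quantile normalization (adjusted p = 0.161). Nor was it called with the replicate block in these 2 groups alone (adjusted p = 0.0535) or with weights per group (adjusted p = 0.0514).

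Of 16 genes of overflow and acetoin metabolism, 13 rose and 1 fell in NaCl_GB (camera adjusted p = 0.0136; adjusted p = 0.81 with an estimated correlation). The lactate permease gene lctP rose by 2.49 ± 0.32, the lactate dehydrogenase gene ldh by 1.91 ± 0.21 and the acetate kinase gene ackA by 1.73 ± 0.19. Of 15 glycolysis genes, 12 rose and 0 fell, gapA by 0.89 ± 0.10 and pdhC by 0.87 ± 0.12 among them (0.0177; adjusted p = 0.81 with an estimated correlation). Of 18 potassium and sodium transport genes, 14 rose and 2 fell, with mrpA at 2.45 ± 0.13 and mrpB at 2.35 ± 0.17 (0.0136; adjusted p = 0.81 with an estimated correlation). Of 25 sulfate and cysteine genes, 17 rose and 4 fell (19 and 4 adjusted over the list alone). Here ytmI rose by 1.18 ± 0.28, and ssuC and ssuB of sulfonate uptake lay at -1.65 ± 0.22 and -1.23 ± 0.23 (0.0305; adjusted p = 0.81 with an estimated correlation). Without reference replicate 2 the sulfate list was not called (adjusted p = 0.131), nor was it with weights per group (adjusted p = 0.0514). It was also not called with the replicate block in these 2 groups alone (adjusted p = 0.0516). There ytmI kept its change but was not called (adjusted p = 0.0598).

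In the sigma W cell envelope regulon, 16 of 47 members fell and 6 rose (13 and 6 adjusted over the list alone), with yndN (fosB) at -1.84 ± 0.13 and sigW at -1.16 ± 0.09 (camera adjusted p = 0.00618; adjusted p = 0.81 with an estimated correlation). In the phosphate starvation list 9 of 19 fell and 2 rose, with pstS at -2.31 ± 0.48 and phoA at -1.75 ± 0.15 (0.0142; adjusted p = 0.81 with an estimated correlation). Without reference replicate 1 it was not called (adjusted p = 0.0563). In the PBSX list, 1 of 30 genes rose (xkdA, 1.23 ± 0.18) and 2 fell (1 and 1 adjusted over the list alone). Camera compared the list with all other genes and gave 0.00861 (adjusted p = 0.81 with an estimated correlation) on a median of -0.95 relative to all genes. Array medians of this list overlapped between the 2 groups. Without reference replicate 2, 8 genes fell and the list was not called (adjusted p = 0.081), nor was it by fry (adjusted p = 0.243). Without reference replicate 3, 19 genes fell, and without any 1 of the NaCl or NaCl_GB arrays, 1 did.

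**Figure D2:**
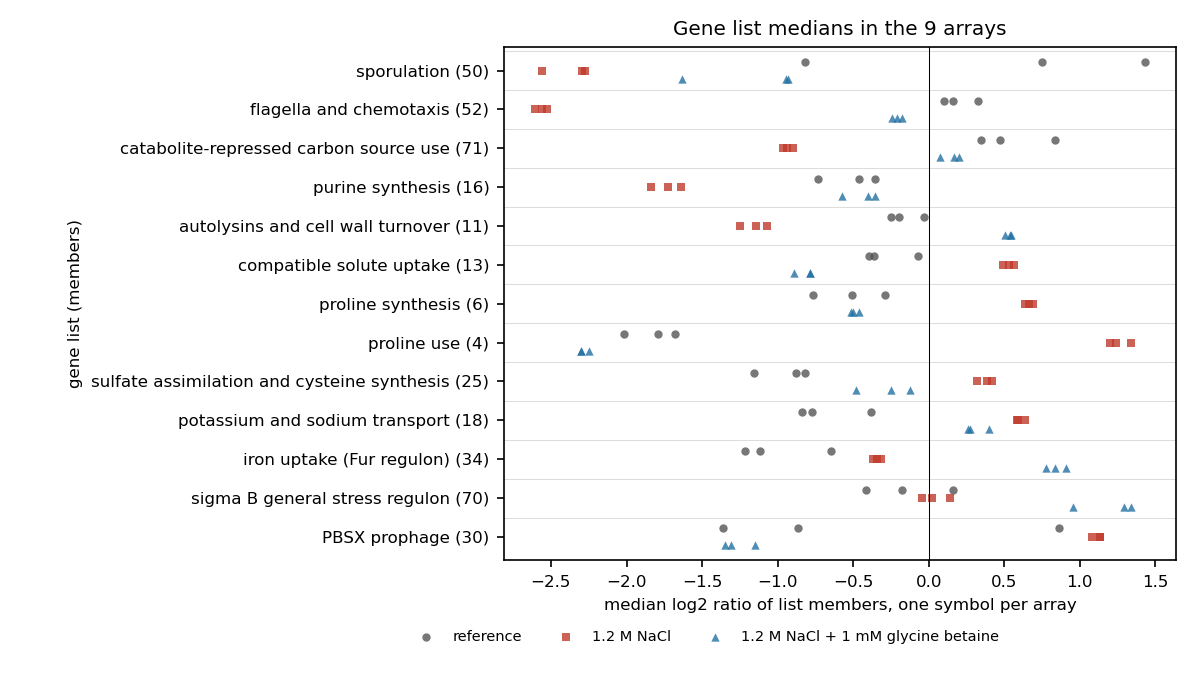
Median log2 ratio of sample to pool over the members of 13 gene lists (horizontal axis), with the number of measured members after each name (vertical axis) and 1 symbol per array. The 3 NaCl arrays lie far below the others for flagella and chemotaxis, the 3 NaCl_GB arrays lie above the others for the sigma B regulon, and the 3 reference arrays spread widely for sporulation and PBSX.

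In NaCl_GB against reference, 2620 genes (63.8%) were called, 1533 higher and 1087 lower, and 1082 changed at least 2-fold. The share of false calls among them was not estimated. Data simulated with no effect gave 20.1 called genes on average in this comparison. That count does not carry over to the measured data, since the adjusted p threshold is less strict per gene when many genes change. The simulation with changed genes, in which false calls exceeded the allowed share, was run only for NaCl against reference. The arrays of the 2 groups did not overlap for 2655 genes (64.7%, against 10% by chance), nor for any gene named above as changed in this comparison. For the largest rises and falls the naming rule required this. The median change of all genes was 0.10, and after centring each array 2590 genes were called, 51.2% of them higher against 58.5% before. Of the 43 lists, 12 were called, 6 up and 6 down, and the array medians of the 2 groups were separate in 11 of these. With an estimated correlation camera called 0 lists, and 0 had an unadjusted p under 0.05.

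The third comparison, NaCl_GB against NaCl, asks what the added glycine betaine changed at the same salinity. Motility genes rose, with 51 of 52 members of the flagella and chemotaxis list higher in NaCl_GB and 0 lower (camera adjusted p = 1.04e-29; adjusted p = 0.185 with an estimated correlation). Their median lay at 2.26 relative to all genes, with hag at 5.04 ± 0.21 (33-fold), mcpA at 3.96 ± 0.10 and motA at 3.79 ± 0.29. All 4 genes of proline use fell (0.000233; adjusted p = 0.185 with an estimated correlation). Of these, ycgM lay at -4.99 ± 0.21 (31.8-fold lower), ycgN at -4.28 ± 0.13, ycgO at -2.81 ± 0.07 and ycgP at -1.96 ± 0.11. The genes that rose most in NaCl, yqiI and yqiH, lay at -4.90 ± 0.20 and -4.69 ± 0.49, and the aminopeptidase gene ywaD at -2.73 ± 0.12.

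Of 13 genes for uptake of compatible solutes, 12 fell and 0 rose, with a median change of -1.02 (camera adjusted p = 4.47e-06; adjusted p = 0.185 with an estimated correlation). Among them, opuE lay at -1.94 ± 0.20, opuAA at -1.91 ± 0.13, opuBA at -1.61 ± 0.10, opuCA at -1.33 ± 0.08, opuAB at -1.32 ± 0.10 and opuAC at -1.21 ± 0.10. The transporter gene opuD, at -0.27 ± 0.14, was not called, but was called without reference replicate 2. The mean was -0.80 ± 0.08 over the opuC operon and -1.06 ± 0.10 over the opuB operon. In proline synthesis, 5 of 6 genes fell (0.0304; adjusted p = 0.569 with an estimated correlation). Here proJ and proH lay at -2.06 ± 0.28 and -2.05 ± 0.33, proG at -0.88 ± 0.11, proB at -0.78 ± 0.12 and proA at -0.69 ± 0.13, while proI, at 0.01 ± 0.10, was not called. All 4 genes of the list of glycine betaine synthesis from choline fell (0.0215, and adjusted p = 0.569 with an estimated correlation). They were the regulator genes yvbF at -2.52 ± 0.09 and yuaC at -1.26 ± 0.14, and the enzyme genes gbsA at -0.93 ± 0.24 and gbsB at -0.82 ± 0.23. The calls of gbsA and gbsB were lost after quantile normalization (-1.03 and -0.89), and that of gbsB also without NaCl replicate 1 or 2 (-0.81 and -0.79) or NaCl_GB replicate 1 or 3 (-0.77 and -0.82).

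Other lists that were higher with glycine betaine covered stress, carbon use and the cell wall. In the sigma B regulon 60 of 70 members rose and 0 fell, at 1.22 relative to all genes (camera adjusted p = 5.41e-15; adjusted p = 0.639 with an estimated correlation). The largest were yqgZ (mgsR) at 2.70 ± 0.24 and ywjC at 2.35 ± 0.26. Of 71 genes for use of other carbon sources, 55 rose and 3 fell, with the glycerol genes glpF at 3.45 ± 0.15 and glpK at 2.71 ± 0.15 (1.35e-11; adjusted p = 0.689 with an estimated correlation). Genes of related lists that were not called also rose. The acetoin dehydrogenase genes acoA, acoB and acoC rose by 3.84 ± 0.22 to 3.90 ± 0.22, gapB, the glyceraldehyde-3-phosphate dehydrogenase gene of gluconeogenesis, by 3.10 ± 0.29, and the glucose permease gene ptsG by 3.08 ± 0.52. Of 16 purine genes, 14 rose and 1 fell (14 and 2 adjusted over the list alone), with pbuX at 2.80 ± 0.16 and xpt at 2.30 ± 0.13 (4.83e-06; adjusted p = 0.639 with an estimated correlation). Of 11 genes of autolysins and wall turnover, 9 rose and 0 fell, with lytF at 3.58 ± 0.09, lytC at 1.99 ± 0.09 and lytA at 1.92 ± 0.08 (1.87e-05; adjusted p = 0.185 with an estimated correlation). In the Fur regulon 21 of 34 rose and 2 fell, with ykuO at 2.95 ± 0.10 and feuA at 2.88 ± 0.19 (3.56e-05; adjusted p = 0.689 with an estimated correlation).

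Of 50 sporulation genes, 12 rose and 0 fell with glycine betaine (11 and 0 adjusted over the list alone; camera adjusted p = 0.000553; adjusted p = 0.722 with an estimated correlation). Rises were largest for cotG at 5.60 ± 1.06, cotX at 5.43 ± 0.94 and cotY at 5.22 ± 0.84. The sizes of these rises rest on the very low ratios of the coat genes in NaCl and are uncertain for that reason. The number that rose was 25 without reference replicate 1 and 35 without reference replicate 2, arrays that enter here only through the shared spread. The list was not called after quantile normalization (adjusted p = 0.222) or by fry (adjusted p = 0.102).

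Among lists that were lower with glycine betaine, 29 of 30 PBSX genes fell, at -2.29 relative to all genes (camera adjusted p = 1.71e-06; adjusted p = 0.689 with an estimated correlation). The largest falls were those of xpf at -3.21 ± 0.57, xkdB at -2.91 ± 0.48 and xkdC at -2.70 ± 0.41. The gene xtrA, which lies among them but is not in the list, lay at -2.75 ± 0.45. All 11 genes of branched-chain amino acid synthesis fell, with leuD at -0.90 ± 0.11 and ilvD at -0.79 ± 0.09 (0.000666; adjusted p = 0.488 with an estimated correlation). Of 25 sulfate and cysteine genes, 20 fell and 2 rose, with ytmI at -2.35 ± 0.28 and ssuC at -1.74 ± 0.22 (0.000274; adjusted p = 0.526 with an estimated correlation). Of 36 genes for antimicrobials, 18 fell and 4 rose (19 and 4 adjusted over the list alone; 0.0117; adjusted p = 0.639 with an estimated correlation). There ywfB of bacilysin synthesis lay at -2.08 ± 0.07 and sboA, the subtilosin precursor gene, at -1.75 ± 0.15. In the sigma W regulon 26 of 47 fell and 1 rose, with pbpE at -0.95 ± 0.09 and yuaI at -0.93 ± 0.10 (8.24e-05; adjusted p = 0.185 with an estimated correlation). The number that fell was 40 without reference replicate 2, 15 without NaCl replicate 2, 14 without NaCl replicate 3 and 16 without NaCl_GB replicate 3.

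In this comparison 2247 genes (54.7%) were called, 1032 higher and 1215 lower, and 846 changed at least 2-fold. A fit to these 2 groups alone, without the wider spread of the reference arrays, called 3129. The arrays of the 2 groups did not overlap for 3278 genes (79.9%, against 10% by chance), nor for any gene named as changed here. For the largest rises and falls the naming rule required this. The median change of all genes was -0.02, and after centring each array 2338 genes were called, with 54.7% of called genes higher against 45.9% before. Of the 43 lists, 16 were called, 7 up and 9 down, each with separate array medians in the 2 groups. With an estimated correlation camera called 0 lists, and 5 had an unadjusted p under 0.05.

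The design sets the comparisons beside each other to ask which salt responses glycine betaine opposed. Of the 3026 genes changed in NaCl, 1609 (53.2%) changed in the opposite direction in NaCl_GB against NaCl. These were 992 that were higher in NaCl, among them yqiI, ycgM, opuE and proH, and 617 that were lower, among them hag, motA, lytF and pbuX. Simulated data with no effect and the same shared NaCl arrays gave 0.01 such genes on average and 1 at most, and independent lists of these sizes would share 841. The changes in the 2 comparisons correlated across genes at r = -0.749 (-0.139 in the simulation), with a covariance of -1.22 (-0.0059 in the simulation). Of the same 3026 genes, 2001 (66.1%) changed in the same direction in NaCl_GB against reference. They were 1174 that were higher, among them dhbB, mrpA and opuE, and 827 that were lower, among them wapA, sspG and opuCA. The simulation gave 14.5 such genes on average and 42 at most, and independent lists would share 997.5. Here the changes correlated at r = 0.789 (0.916 in the simulation) with a covariance of 1.38 (0.0968 in the simulation). Each pair of comparisons shares 3 arrays that cannot be split between them, so part of either excess may come from the shared arrays. The simulation called only 18.1, 20.1 and 0.02 genes on average in the 3 comparisons, so its overlaps had to be small. They do not show how much overlap shared arrays give when as many genes are called as here. A further 457 genes were called in NaCl_GB against reference and not in NaCl against reference, 266 higher and 191 lower. Another 69 genes were higher in NaCl and lower in NaCl_GB against reference, and 93 the reverse.

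**Figure D3:**
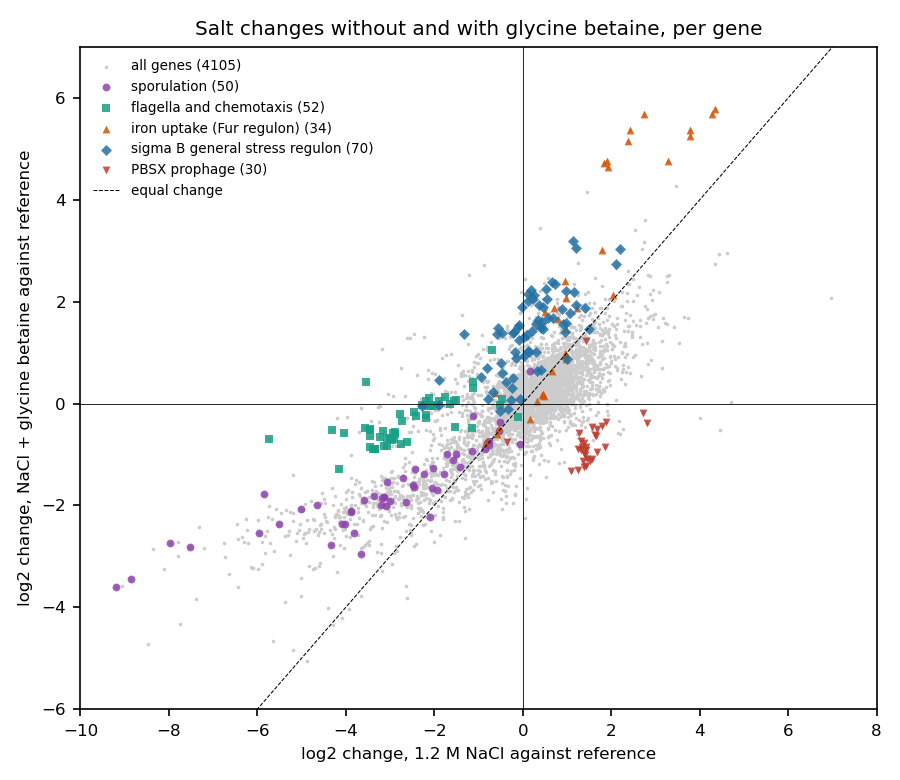
Log2 change in NaCl against reference (horizontal axis) and in NaCl_GB against reference (vertical axis) of 4105 genes, 1 point per gene, with 5 gene lists marked and a dashed line of equal change. Sporulation genes were mostly lower on both axes and flagella and chemotaxis genes lower mainly in NaCl, while sigma B genes were higher mainly in NaCl_GB; both axes share the 3 reference arrays.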

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

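The tests with weights per group, with the unnamed probes and with a block in 2 groups alone were chosen only after the results were seen; all other alternatives here were planned. Over 544 changes of named genes, 445 kept their direction and side of the threshold in every setting run, 92 missed the threshold in at least 1 setting, 6 passed it only in an alternative, and 1 reversed. The reversal was tasA in NaCl against reference, at -1.35 in the main analysis and 0.95 after quantile normalization; the cause was not tested. Of 129 list results, 36 kept their call or lack of one in every setting, 42 called lists missed the threshold in at least 1, 51 passed only in an alternative, and 0 reversed.

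With a minimum change of 2-fold, by construction fewer genes were called: 1566 in NaCl against reference, 1082 in NaCl_GB against reference, 846 in NaCl_GB against NaCl, 1905 in the F test, 606 opposed by glycine betaine and 804 changed alike in both salt groups. Camera with an estimated correlation called 0, 0 and 0 lists in these comparisons, where 1, 0 and 5 had an unadjusted p under 0.05. The only setting that differed from the main list test was the correlation between genes, estimated here and preset at 0.01 there. The list calls of the main analysis thus depend on that preset. By fry, which asks whether the genes of a list move on balance and does not compare them with other genes, 31, 30 and 26 lists were called.

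Leaving out 1 array at a time gave 2714 to 3302 called genes in NaCl against reference, 2139 to 3089 in NaCl_GB against reference and 1784 to 2856 in NaCl_GB against NaCl. The F test then gave 3148 to 3705, the opposed genes 1289 to 2025, the genes changed alike 1634 to 2441, and the lists 10 to 15, 11 to 14 and 16 to 17. With a replicate block, the paired fit, the counts were 2969, 2559 and 2178, with 3370 in the F test, 1564 opposed, 1958 changed alike and 14, 12 and 17 lists. Fitted alone with a replicate block, these 2 groups gave 2005 genes, 1986 of them with the sign of the main analysis, and 10 lists. Of the changes of named genes in that comparison, 154 kept their side of the threshold in this paired fit and 25 missed it; with complete pairs the size of a change stays the same by construction. It changed the calls of 2 of the 43 lists, proline use and sulfate, and of no other. Fits to only the 2 groups compared gave 2767, 2061 and 3129. Weights per array gave 2601, 1982 and 3339, the last above every other count for NaCl_GB against NaCl, but reference replicate 3 received a weight of 0.000249 and so hardly counted. Weights per group gave 2721, 2141 and 3159, with 3571 in the F test, 1948 opposed, 1621 changed alike and 15, 10 and 17 lists. In simulated data with no effect and the measured spread of each group, the unweighted model called 18.1 and 20.1 genes on average in the comparisons with the reference and 0.02 in the other. These counts do not give the number of false calls in the measured data, where many genes change. Among the unnamed probes, 57.1%, 43.8% and 37.4% were called. A filter on low values was not run, since ratios hold no level, and the probe table per gene and the mean in place of the median of probes were not run, since the probes carry no gene names. Signal over background, which limits the precision of single spots, was not analysed here.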

Other observations

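The tests on sporulation genes, on genes below the pool and on the scale of the arrays for PBSX, and the runs and the ratios above 9 described below, were chosen only after the results were seen.

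Runs of neighbouring genes moved together by at least 2-fold. In NaCl against reference, several lay in the region of the prophage SPβ: 27 genes from yosQ to yorO fell, with a median change of -2.56, as did 18 genes from yonD to yomM (-2.53), 14 from yotK to yosW (-2.00) and 11 from yonX to yonJ (-1.99). The longest run in 100 shuffles of the gene order had 7 genes. Median log2 ratios of the run from yosQ to yorO were 1.05, 2.12 and 1.64 in the 3 reference arrays, -1.01, -0.97 and -1.13 in NaCl, and -0.63, -0.42 and -0.33 in NaCl_GB. In NaCl the genes of these runs thus went the other way from those of PBSX, but 5 genes of the same region from bdbB to sunA, with sublancin synthesis, rose (1.74), a run no longer than those in shuffles. A run of 23 genes from cotJA to lplB, with the yes genes of pectin and rhamnogalacturonan use, fell (-2.72), and 13 genes from deaD to wapA fell in NaCl (-2.92) and in NaCl_GB (-2.94). Runs that rose in NaCl, in part made of list members, included 13 genes from srfAA, of surfactin synthesis, to yckJ (1.74) and 9 from sboA to albG of subtilosin synthesis (1.39). Another was 11 genes from ribR to ytlI (2.09), which lay at -1.47 in NaCl_GB against NaCl. In PBSX, 15 genes from xkdB to xkdM (1.43) and 13 from xkdP to xlyA (1.45) rose. So did runs of 8 genes from sacV to yddA (1.45), yurJ to yurQ (1.54) and yxeR to yxeK (1.57).

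Members of lists that were not called also changed in NaCl against reference. The mechanosensitive channel gene mscL rose by 2.15 ± 0.11, the levansucrase gene sacB by 2.75 ± 0.13 and the neutral protease gene nprB by 2.66 ± 0.08, while the minor protease gene epr lay at -5.20 ± 0.08, the catalase gene katA at -1.83 ± 0.08 and ythA of a terminal oxidase at -2.97 ± 0.48. In the ribosomal protein list 17 of 53 members rose and 4 fell (15 and 1 adjusted over the list alone), with a median of -0.01 and a camera p of 0.850. In the SOS list 10 of 16 rose and 0 fell (9 and 0 adjusted over the list alone).

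For the comparisons of 3 arrays against 3, 10 splits of the 6 arrays exist, too few for a share under 0.05. Fitted to the 6 arrays alone, the real split gave 2767 genes in NaCl against reference, 2061 in NaCl_GB against reference and 3129 in NaCl_GB against NaCl, and 1 of 10 splits, the real one, reached each of these values; the highest other split gave 0 in each. For the F test, 1 of 100 splits of the 9 arrays into 3 groups of 3, the real one, reached 3421 genes and the highest other gave 1441. Chance assignment of the arrays is thus unlikely to give that count, but 100 drawn splits bound its share only at 1 in 100.

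Sporulation genes differed between the 3 reference arrays, with list medians of 1.44, -0.82 and 0.75 in replicates 1, 2 and 3. Noise of the reference arrays in general did not account for this: the median SD of the list was 4.96 times that of other genes, against at most 1.67 in 10000 random lists. Nor did array scale, since median centring narrowed the gap between the highest and lowest list median by -3.82%, that is, widened it slightly. A hypothesis that stays open is that the cultures held different shares of sporulating cells, which may be why 98% of the members (49 of 50) had the same order of the 3 arrays. Any other factor that moves these genes together would give the same order and was not tested.

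PBSX genes were higher in NaCl than in NaCl_GB by a list median of -2.31 (NaCl_GB minus NaCl). Array scale did not account for this, since the median stayed at -2.21 after centring. An SOS response, which induces this prophage, could not be decided. The SOS list median was -0.41 with an unadjusted camera p of 0.281, between the bounds set before the result was seen. Of the 16 SOS genes, 8 fell in NaCl_GB against NaCl. Only 4 or 5 fell, and 1 or 2 rose, without NaCl replicate 1 or 3 or NaCl_GB replicate 1 or 3. List medians of PBSX were -0.86, 0.86 and -1.36 in the 3 reference arrays, so cultures without salt also differed. Salt and glycine betaine themselves may act on the prophage, and that stays open and untested.

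A total of 34 genes had a ratio below 0.5 to the pool on all 9 arrays, although the pool was made from these samples, and 0 genes lay above 2 on all 9; the limit of 0.5 was chosen after seeing that limits of 1/3 and 2/3 gave 22 and 67 genes. They included 14 of 20 genes of the matrix list, with tasA at 0.124 or less and sipW at 0.0766 or less, comGA to comGG, and gntR, gntK and gntP, with a median over the set of 0.225 for the mean of 9 ratios. Array scale did not account for the set, since the mean ratio had a median of 1.07 over all genes, and nor did a bias of single probes or genes, since 31 of the 34 had a neighbour in the set, against at most 6 in 10000 shuffles. RNA of other cultures in the pool, or a different response of whole transcripts to the dyes, may account for the set; neither was tested. If signals are proportional to RNA, changes between groups do not depend on the level of the pool, but the ratios of these genes do. Whether that holds for genes so far below the pool was not tested, so their changes are less certain. The change of tasA, a member of the set, reversed in NaCl against reference after quantile normalization.

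With a pool of equal parts of 9 samples, a ratio above 9 is not expected, yet 9 genes exceeded it in reference replicate 1, with cotG at 35.7, 1 in NaCl_GB replicate 1 (ybyB, 9.21) and 1 in NaCl_GB replicate 2 (yhjK, 9.85). The mean of the 9 ratios lay within 1.5-fold of 1 for 3486 genes (84.9%).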
